A study of Mus musculus with 6 samples.

How the data were processed

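Total liver RNA of 6 samples was measured on Affymetrix whole-transcript arrays, 1 array per sample. Per the labels' protocols, RNA was isolated with a silica column kit, and biotin-labelled cRNA was made from 100 ng of total RNA with the manufacturer's whole-transcript kit. Per the submitters' processing notes, Affymetrix Expression Console 1.4.1 and RMA were used. RMA corrects the background of each array, sets the probe intensities of all arrays to a common distribution and summarises the probes of a probe set into a log2 value. The deposited table holds these log2 expression values made by the authors, 41345 probe sets on each of the 6 arrays, and the array medians lay between 3.11 and 3.16. Because RMA sets the arrays to a common distribution, a shift of most transcripts in the same direction would not be visible in these values. The arrays were not normalized again for the main comparison. No genome build or probe position is given in the sources used here, so no coordinates are printed.

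Probe sets were named with the annotation of the array platform. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not in that annotation. Symbols were checked against a RefSeq gene table of the mouse assembly GRCm38.p6, in which the gene numbers of 23328 probe sets were found, and 0 symbols needed an update. Only probe sets with 1 gene symbol entered the gene test. For the 1082 genes with several such probe sets, the probe set with the highest mean over the 6 arrays was used, which left 22180 genes. No filter on dim probe sets was applied in the main comparison. Whole-transcript probe sets of near-identical genes, such as the Cyp2b, Saa, Mup, Cyp4a, Orm and Acot families, can share probes or cross-hybridise, so values of single members of these families are uncertain.

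The labels give 2 groups of 3 arrays, knockout and control, with replicate numbers 1 to 3 in each group. No pair of arrays held identical values (0 pairs). The labels do not say that the replicates were separate animals, so p-values measure only the spread between these samples, which can be technical in part. The small number of arrays limits the precision of every value.

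The comparison was a linear model of log2 expression on group with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for the robust and block fits. P-values are 2-sided and adjusted by the Benjamini-Hochberg method over the 22180 genes, with a threshold of 0.05. Differences are knockout minus control on the log2 scale, given with the standard error of the model. As a description of size, genes at an unadjusted p under 0.05 with at least a 1.5-fold difference were also counted. For Prkg1 an exact 2-sided permutation test was added.

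There were 35 gene lists, written from general knowledge of liver biology before the data were examined. They cover pathways of hepatocyte metabolism, stress and inflammation, and markers of the cell types that a liver sample can hold, with adipose, pancreatic and intestinal markers for neighbouring tissue. Of the 743 list entries, 665 were matched to a tested gene, 2 of them through another symbol, and 78 were not matched. Lists were tested with camera of limma on the moderated statistics of the same model, with a preset inter-gene correlation of 0.01 and adjustment over the 35 lists. The same test with an estimated correlation, and fry, were run as alternatives. Fry tests whether the genes of a list move, on balance, in the same direction, without comparing the list with other genes. Members of each list were also tested with p-values adjusted over the list alone.

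The genes to be named were fixed by a rule before the data were examined. The rule takes Prkg1, then up to 12 genes in each direction. Where fewer than 12 pass the threshold, it fills the places with the non-passing genes of smallest p that differ at least 1.5-fold and are not predicted gene models. In each list it takes up to 6 members past the threshold over all genes and otherwise the members with the largest moderated statistic, up to 4. Further genes named outside this rule are marked as chosen after their values were seen; the genes of the tests in the closing section are named there because a test used them.

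The gene test and the list test were tested on simulated data with the tested genes and group sizes, in which 200 of 22180 genes were shifted. Gene variances were drawn from the distribution fitted to the real arrays, equal in both groups, and only brighter genes were shifted. At an adjusted p under 0.05 the test recovered 72% of the 50 genes shifted by 1 log2 unit. At each of the shifts of 2, 3 and 4 it recovered 100% of the 50 genes. There were 8 calls among unshifted genes. The real knockout arrays spread more than the controls (median standard deviation of a gene 0.193 against 0.146), so these shares can be higher than on the real arrays. There, Lcn2 (log2 difference 3.70) and Elovl3 (-3.70) did not pass. Of 99 unshifted lists, 1 had a camera p under 0.05, but the simulated genes varied independently, so this does not describe the test on real lists, whose genes are correlated. In the real data, splits of the arrays that mix the groups gave 4 to 13 called lists. Each such split sets 2 knockout and 1 control array against 1 knockout and 2 control arrays. It therefore keeps part of the group difference, and these counts are not a rate of false calls.

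Alternatives fixed before the data were examined were leaving out each replicate in turn, the replicate number as a block, a filter on probe sets at or below the median level of the table, a further quantile normalization, centring on array medians, an intensity trend or a robust setting in the variance prior, array weights, averaging the probe sets of a gene, testing every probe set, and other size and significance thresholds. Chosen after seeing the data were the count at an adjusted p under 0.10 and list tests without members shared between lists. Probe sets with several gene symbols or without an annotation, and the further probe sets of genes already tested, were left out of the gene test and tested apart.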

Results

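Gene expression was measured in the liver of male C57BL/6N mice aged 2 months, in 3 samples from mice lacking cGMP-dependent protein kinase 1 (cGK1, encoded by Prkg1) and 3 samples from control mice. The knockout mice carried a rescue of the kinase in smooth muscle, per the series description, which names control mice where the sample labels say wild type. The comparison addressed how liver expression differs when the kinase is missing outside smooth muscle. The series title concerns activation of hepatic stellate cells, the vitamin A-storing cells that can become collagen-producing cells. Values are log2 RMA expression on 1 array per sample, and n = 3 per group throughout. Array medians lay between 3.11 and 3.16. Across genes, which are not independent replicates, correlations were 0.989 to 0.990 among control arrays, 0.978 to 0.983 among knockout arrays and 0.978 to 0.983 between the groups. Knockout replicate 3 correlated better with each control array (0.981 to 0.983) than with knockout replicates 1 and 2 (0.978 and 0.979). On the first principal component, which held 33.3% of the variance, control arrays lay at 17.7, 21.5 and 17.1 and knockout replicates 1 to 3 at -29.9, -23.9 and -2.50. On this component knockout replicate 3 lay nearer to the controls than the other knockout arrays did. The second component held 23.3% of the variance and set knockout replicate 3, at 36.0, apart from all other arrays. Control arrays lay there at -3.03, -10.4 and -4.14 and knockout replicates 1 and 2 at 0.22 and -18.6. The median standard deviation of a gene was 0.193 in the knockout group and 0.146 in the control group.

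Prkg1 itself did not differ detectably between the groups. Its expression was 3.31, 3.04 and 3.22 in the knockout arrays and 3.32, 2.97 and 2.95 in the control arrays, with means of 3.19 ± 0.14 and 3.08 ± 0.21 (SD). The log2 difference was 0.11 with a standard error of 0.15 and a 95% confidence interval of -0.23 to 0.45, which spans a 0.850- to 1.36-fold ratio, and limma gave an adjusted p of 0.837. The exact permutation test gave p = 0.6, with 0.1 as the smallest p that 3 against 3 arrays allow. The mean lay at percentile 41.1 of all tested genes. The control mean lay just under the limit of the dim filter (3.11), so the signal was dim and a loss could hardly show. The probe set covers the whole transcript, the deleted exon is not given in the sources used here, and the rescue may add Prkg1 transcript. For these reasons this value does not check the genotype labels.

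The genes with the strongest evidence of higher expression in the knockout were Apcs, encoding the acute phase protein serum amyloid P, Gucy2c, encoding a receptor guanylate cyclase that produces cGMP, and Lcn2, encoding the iron-siderophore binding protein lipocalin 2. Apcs lay 4.40-fold higher (log2 difference 2.14, SE 0.23, limma adjusted p = 0.0613), Gucy2c higher by 1.199 (SE 0.13, adjusted p = 0.0613) from a control mean of 3.11, just under the limit of the dim filter, so that the size of its difference is uncertain, and Lcn2 13.0-fold higher (3.70, SE 0.44, adjusted p = 0.0674). The genes with the strongest evidence of lower expression were the ion channel gene Asic5 (log2 difference -1.34, SE 0.15, adjusted p = 0.0613), the retinol saturase gene Retsat (-1.05, SE 0.13, adjusted p = 0.0761) and Pex11a, which acts in peroxisome proliferation (-0.90, SE 0.12, adjusted p = 0.0826). None of these passed the threshold of 0.05.

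The other genes named by rank as higher were Slc13a3 (1.36), Tff3 (1.22), Phf11b (1.195), the proton pump subunit gene Atp6v0d2 (1.82), the heme oxygenase gene Hmox1 (0.96), the cytochrome P450 gene Cyp2b9 (5.90), the lipoprotein lipase gene Lpl (1.48), the type III collagen gene Col3a1 (0.86) and Atp11a (0.97), each with its log2 difference and adjusted p-values up to 0.130. Cyp2b9 had the largest of these differences, against a control mean of 2.97 in the dim part of the table, so its fold is uncertain, and without knockout replicate 3 the difference was 7.09 and without knockout replicate 2 it was 5.27. The control mean of Atp6v0d2, 3.11, was also dim. For Atp11a a second, dimmer probe set gave -0.15. Those named as lower were the small heat shock protein gene Hspb1 (-1.75), the fatty acid elongase gene Elovl3 (-3.70), the efflux transporter gene Abcg2 (-0.92), the lipid droplet gene Plin5 (-1.01), Mfsd4b3-ps (-0.83), the acyl-CoA thioesterase gene Acot1 (-1.70), Ugt3a1 (-1.01), the succinate receptor gene Sucnr1 (-1.22) and the peroxisomal thiolase gene Acaa1b (-1.20), with adjusted p-values up to 0.133. A second, dimmer probe set of Hspb1 gave -0.32. In all 24 genes the 3 knockout values lay outside the range of the 3 control values, which choosing genes by the smallest p makes likely.

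**Figure D1:**
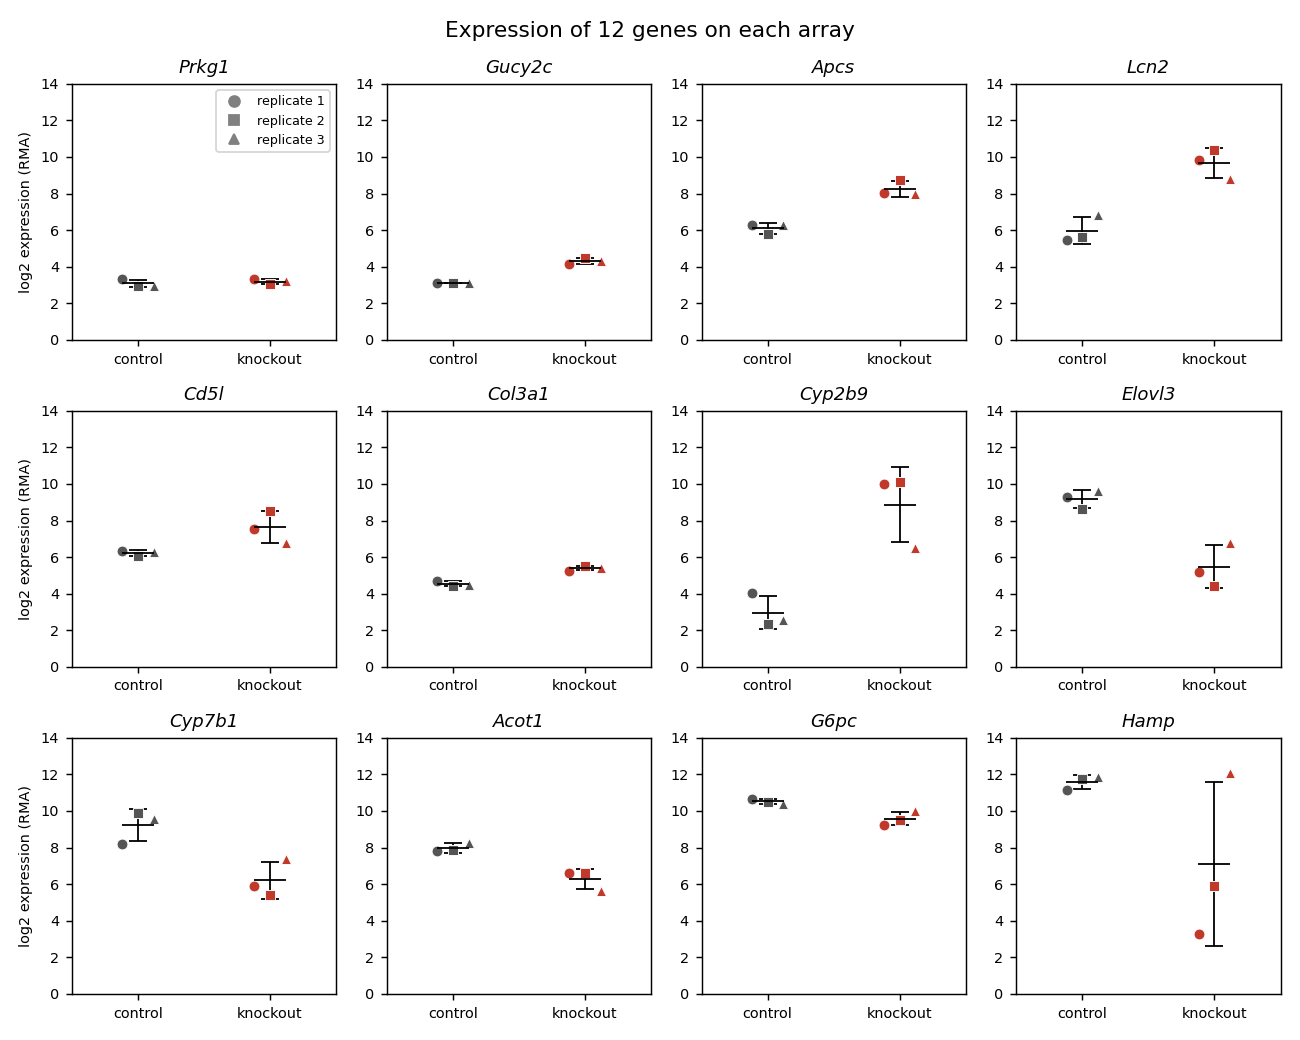
Log2 RMA expression of 12 genes on each array (vertical axis, 0 to 14), with the 3 control arrays in grey and the 3 knockout arrays in red. Symbols mark the replicate number, the long bar is the group mean and the short bars are the standard deviation. Prkg1 overlaps between the groups at about 3, and Hamp lies near 12 in the controls and at 3.30, 5.92 and 12.1 in knockout replicates 1, 2 and 3.

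Over all genes, 0 of 22180 passed an adjusted p of 0.05 in limma, the smallest being 0.0613, while 2334 genes lay at an unadjusted p under 0.05, where 1109 are expected with no difference. Of these, 587 differed at least 1.5-fold, 330 higher and 257 lower in the knockout. This excess of higher genes depended on the processing. There were 294 higher and 291 lower after centring on array medians, and 215 higher and 222 lower with the filter on dim probe sets. Further quantile normalization widened the excess, to 336 higher and 218 lower. The groups did not overlap in 16.7% of genes, where chance gives 10%. At an adjusted p under 0.10, a threshold chosen after seeing the data, there were 19 genes, 10 higher and 9 lower. The count depended on single arrays and on the variance model. Without knockout replicate 3, 66 genes passed 0.05 (30 higher, 36 lower), without control replicate 3, 3 genes did, and without any of the other 4 arrays 0 did. With a filter on dim probe sets 15 genes passed, and with an intensity trend in the variance prior 25, and these held 15 and 21 of the 24 genes named by rank.

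Genes of the acute phase response, the liver's secretory answer to inflammation, were higher in the knockout as a group. Of 24 measured members, 22 had positive differences with a median of 0.55 (1.46-fold), and camera gave an adjusted p of 3.18e-16, against an adjusted p = 0.280 with an estimated correlation. Over all genes 0 members passed, while adjusted over the list alone 18 were higher and 1, Hamp, was lower. Hamp was lower only in knockout replicates 1 and 2 (3.30 and 5.92), and knockout replicate 3 (12.1) lay above the controls (11.1 to 11.8). Beside Apcs and Lcn2, the strongest were Orm2, an orosomucoid gene (3.46, SE 0.57, limma adjusted p = 0.139 over all genes), and the metallothionein gene Mt2 (1.42, SE 0.24, adjusted p = 0.151). Saa2, a serum amyloid A gene chosen after its values were seen, was 15.1-fold higher (3.91, SE 0.86, adjusted p = 0.237), at 10.3, 12.4 and 8.26 in knockout replicates 1 to 3 against 5.51 to 7.25 in the controls. The size of the differences depended on single arrays, with Saa2 at 2.88 without knockout replicate 2 and 4.93 without knockout replicate 3, and Orm2 at 2.70 without knockout replicate 2.

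Markers of macrophages and Kupffer cells, the resident macrophages of the liver, were also higher, with 22 of 24 differences positive, a median of 0.76 (1.70-fold) and a camera adjusted p of 7.26e-12, against an adjusted p = 0.280 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 14 were higher and 0 lower. The complement gene C1qa differed by 0.84 (SE 0.17, limma adjusted p = 0.221), the scavenger receptor gene Marco by 0.74 (SE 0.18, 0.249), and Cd68 by 0.98 (SE 0.25, 0.266), and Cd5l was 2.64-fold higher (0.272). Neutrophil markers had a median of 0.29 with 14 of 17 positive (camera adjusted p = 8.91e-05, adjusted p = 0.280 with an estimated correlation). Adjusted over the list alone 4 were higher, namely Lcn2, which hepatocytes also make in the acute phase, and the protease genes Mmp8 (0.74), Prtn3 (0.75) and Mmp9 (0.46), while the median control level of the list was only 2.48 and Mmp8 was dim in both groups. The neutrophil list was 1 of 2 lists that fry called (adjusted p = 0.0102).

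Interferon and antigen presentation genes had a median of 0.28 with 22 of 27 positive (camera adjusted p = 7.37e-05, adjusted p = 0.442 with an estimated correlation). Ly6e (0.93) alone passed when adjusted over the list alone, and Psmb8 (0.56), Gbp7 (0.47) and H2-Q4 (0.45, and 0.03 by a second, dimmer probe set) did not pass. Inflammatory cytokine and chemokine genes had a median of 0.22 with 17 of 22 positive (camera adjusted p = 0.00832, adjusted p = 0.280 with an estimated correlation), and 0 members passed adjusted over the list alone; the largest statistics were those of Icam1 (0.59), Ccl9 (0.47), Vcam1 (0.45) and Nfkbia (-0.42), an inhibitor of NF-kB. Macrophage markers lay higher in the same arrays by a median of 0.76. The interferon call ended without knockout replicate 2 (adjusted p = 0.208, range over 15 alternatives 2.17e-08 to 0.208) and the cytokine call without control replicate 2 (0.0595, range 0.00214 to 0.0595). In these and all later ranges the 15 alternatives leave out the estimated correlation and fry. By fry the adjusted p was 0.402 for the interferon and 0.123 for the cytokine list.

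Genes that are more highly expressed in male than in female mouse liver were lower in these male knockout livers. Of 19 measured members 18 had negative differences, with a median of -1.09 (2.12-fold lower) and a camera adjusted p of 1.00e-14, against an adjusted p = 0.280 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 15 were lower and 0 higher. Elovl3 was 13.0-fold lower (-3.70), Cyp7b1, an oxysterol hydroxylase gene, 8.09-fold lower (-3.02, SE 0.53, limma adjusted p = 0.153), and the fatty acid hydroxylase gene Cyp4a12b differed by -3.14 (SE 0.60, 0.196) and Cyp2u1 by -0.97 (SE 0.20, 0.221). Knockout replicate 3 lay nearer the controls here, and without it the difference was -4.35 for Elovl3 and -3.92 for Cyp4a12b, while without knockout replicate 2 that of Cyp4a12b was -2.50. Mup21, a major urinary protein gene chosen after its values were seen, lay at 1.86, 1.47 and 5.22 in knockout replicates 1 to 3 against 6.15 to 6.62 in the controls. Genes that are more highly expressed in female liver were higher, with 21 of 23 differences positive, a median of 0.33 (1.26-fold) and a camera adjusted p of 1.97e-08, against an adjusted p = 0.280 with an estimated correlation. Adjusted over the list alone 8 were higher and 0 lower, led by Atp6v0d2, Cyp2b9, the organic anion transporter gene Slc22a26 (2.94, SE 0.49, adjusted p = 0.145 over all genes, and 3.64 without knockout replicate 3) and the sulfotransferase gene Sult3a1 (1.01, SE 0.23, 0.237). Sult3a1 lay at 0.86 to 2.44 on all 6 arrays, under the limit of the dim filter, so the size of its difference is uncertain. The median control level of the female-biased list was only 3.19, near that limit (3.11). Control means were 3.11 for Atp6v0d2 and 3.19 for Slc22a26, so the sizes of their differences are uncertain too.

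Genes of xenobiotic metabolism had a median of 0.29 with 20 of 26 positive and a camera adjusted p of 0.00169, against an adjusted p = 0.280 with an estimated correlation. Adjusted over the list alone 6 were higher and 3 lower, among them Cyp2b9, Cyp2b10 (0.98) and the glutathione transferase gene Gstt3 (1.14) as higher, and Aldh1a7 (-0.56) with Ugt2b35 (-0.75) and Aldh1a1 (-0.56), the last 2 chosen after their values were seen, as lower. The list shares members such as Cyp2b9 with the female-biased list, and without members shared between lists, an alternative chosen after seeing the data, its adjusted p was 0.280 (range over 15 alternatives 0.000139 to 0.280).

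Genes of fatty acid oxidation and other targets of the nuclear receptor PPARA were lower in the knockout. Of 25 measured members 24 had negative differences, with a median of -0.62 (1.54-fold lower) and a camera adjusted p of 1.00e-14, against an adjusted p = 0.280 with an estimated correlation. Over all genes 0 members passed. Adjusted over the list alone 17 were lower, and 1, the fatty acid transporter gene Cd36, was higher (1.23, SE 0.31, limma adjusted p = 0.264 over all genes), named after its values were seen. Acot1 was 3.25-fold and Acaa1b 2.30-fold lower, followed by the pyruvate dehydrogenase kinase gene Pdk4 (-1.12, SE 0.22, adjusted p = 0.204) and the mitochondrial carnitine palmitoyltransferase gene Cpt2 (-0.63, SE 0.14, 0.237).

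Other metabolic lists shifted by smaller amounts. Gluconeogenesis and glycogen genes had a median of -0.16 with 14 of 18 negative (camera adjusted p = 0.00240, adjusted p = 0.291 with an estimated correlation), and adjusted over the list alone Pdk4 and the glucose-6-phosphatase gene G6pc (-0.94) were lower, while Ppp1r3b (-0.99) and the phosphoenolpyruvate carboxykinase gene Pck1 (-0.36) did not pass. Ppp1r3b lay at 5.73 and 5.75 in knockout replicates 1 and 2, at 7.28 in knockout replicate 3 and at 7.15 to 7.30 in the controls, so its difference was -1.50 without knockout replicate 3 (adjusted p = 0.00569 over all genes), and a second probe set gave -0.60. De novo lipogenesis genes had a median of -0.24 with 14 of 20 negative (camera adjusted p = 0.00832, adjusted p = 0.280 with an estimated correlation), and adjusted over the list alone the malic enzyme gene Me1 (-0.70) was lower and Thrsp (0.68) higher. Bile acid and sterol handling genes had a median of -0.15 with 13 of 20 negative (camera adjusted p = 0.0395, adjusted p = 0.280 with an estimated correlation). Cyp7b1 was lower adjusted over the list alone, and the transporter gene Slco1a1, at -2.61, did not pass (-3.66 without knockout replicate 3 and -1.64 without knockout replicate 2), both also members of the male-biased list. Oxidative phosphorylation genes had a median of -0.11 with 18 of 22 negative (camera adjusted p = 0.0226, adjusted p = 0.291 with an estimated correlation). Cholesterol synthesis genes had a median of 0.15 with 15 of 17 positive (camera adjusted p = 0.0395, adjusted p = 0.605 with an estimated correlation). In both lists 0 members passed adjusted over the list alone, and the largest statistics were those of Ndufs1 (-0.32) and Sdha (-0.31), and of Msmo1 (0.66) and Hmgcs1 (0.53).

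Each of these 5 metabolic calls ended under some alternatives. Without control replicate 2 the adjusted p was 0.0595 for gluconeogenesis, 0.158 for bile acids, 0.0811 for oxidative phosphorylation and 0.692 for cholesterol synthesis. Without knockout replicate 2 it was 0.0637 for lipogenesis, 0.0713 for bile acids and 0.0719 for oxidative phosphorylation, without knockout replicate 1 it was 0.0685 for bile acids, and without knockout replicate 3 it was 0.109 for oxidative phosphorylation and 0.537 for cholesterol synthesis. The filter on dim probe sets gave 0.0677 for lipogenesis, 0.205 for bile acids and 0.136 for oxidative phosphorylation, further quantile normalization gave 0.0870 for bile acids and 0.112 for oxidative phosphorylation, and leaving out members shared between lists gave 0.132 for gluconeogenesis and 0.268 for bile acids. Over 15 alternatives the adjusted p ranged from 0.000314 to 0.132 for gluconeogenesis, 0.00213 to 0.0677 for lipogenesis, 0.0165 to 0.268 for bile acids, 0.00852 to 0.136 for oxidative phosphorylation and 0.000328 to 0.692 for cholesterol synthesis.

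Collagen and fibrosis genes, which bear on the stellate cell question, were modestly higher. Of 21 measured members 16 had positive differences, with a median of 0.27 (1.204-fold) and a camera adjusted p of 0.000661, against an adjusted p = 0.280 with an estimated correlation. Col3a1 (0.86, SE 0.14, limma adjusted p = 0.130) alone passed when adjusted over the list alone. The matrix protein gene Sparc (0.78), Thbs1 (0.44) and the type I collagen gene Col1a2 (0.60, and 0.34 by a second, dimmer probe set) did not pass. Stellate cell markers had a median of 0.11 with 12 of 14 positive (camera adjusted p = 0.0395, adjusted p = 0.463 with an estimated correlation), and 0 members passed adjusted over the list alone; Ecm1 (0.54), Lhx2 (0.29), Des (0.41) and Rgs5 (0.53) had the largest statistics. Smooth muscle genes had a median of -0.25 with 10 of 14 negative (camera adjusted p = 0.0185, adjusted p = 0.291 with an estimated correlation), and 0 passed; the smooth muscle actin gene Acta2, which activated stellate cells also express, differed by -0.39, Cnn1 by -0.52 and Lmod1 by -0.31. Endothelial markers had a median of 0.15 with 15 of 20 positive (camera adjusted p = 0.0226, adjusted p = 0.605 with an estimated correlation), and Lyve1 (0.92), a marker of sinusoidal endothelium, alone passed adjusted over the list alone, while Cdh5 (0.54) did not.

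The stellate, smooth muscle and endothelial calls each depended on single arrays. Without knockout replicate 2 the adjusted p was 0.881, 0.0713 and 0.983 for the stellate, smooth muscle and endothelial lists. Without control replicate 2 it was 0.153 for the stellate and 0.0583 for the endothelial list, without control replicate 3 it was 0.0829 for the stellate and 0.0846 for the smooth muscle list, and without knockout replicate 3 it was 0.0991 for the smooth muscle list. The filter on dim probe sets gave 0.441 for the smooth muscle list, and leaving out members shared between lists gave 0.0990 for the stellate list. The range over 15 alternatives was 0.00426 to 0.881 for stellate, 0.00322 to 0.441 for smooth muscle and 0.000515 to 0.983 for endothelial markers.

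Genes of the unfolded protein and integrated stress response were lower as a group, with a median of -0.25, 17 of 23 negative and a camera adjusted p of 0.00440, against an adjusted p = 0.369 with an estimated correlation. Adjusted over the list alone 0 passed, and the largest statistics were those of the endoplasmic reticulum genes Herpud1 (-0.75) and Creld2 (-0.68), of Chac1 (0.54) and of the hormone gene Fgf21 (-0.64). Without control replicate 2 the adjusted p was 0.0811 (range over 15 alternatives 2.15e-06 to 0.0811). Heat shock and immediate early genes were not called (median -0.14, camera adjusted p = 0.118), although adjusted over the list alone Hspb1 and the transcription factor gene Jun (-1.25) were lower and Hspa1a (0.62) higher, the last with means of 2.30 and 2.92 in the controls and the knockout, both under the limit of the dim filter. This list passed without knockout replicate 2 (0.0261) and without control replicate 1 (0.0313), within a range of 0.0261 to 0.639. Glucocorticoid and fasting response genes were not called either (adjusted p = 0.136). Their median was -0.37 and their mean 0.02, so median and mean differed in sign, with camera's direction lower. Adjusted over the list alone 3 members were higher, Lcn2, Mt2 and Mt1 (1.19), and 4 were lower, Angptl4 (-0.71) and, chosen after their values were seen, Gadd45b (-0.91), Errfi1 (-0.61) and Fmo5 (-0.52). With shared members removed, an alternative chosen after seeing the data that takes out Lcn2, Mt1 and Mt2 among others, the adjusted p was 3.03e-05 (range 3.03e-05 to 0.543).

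**Figure D2:**
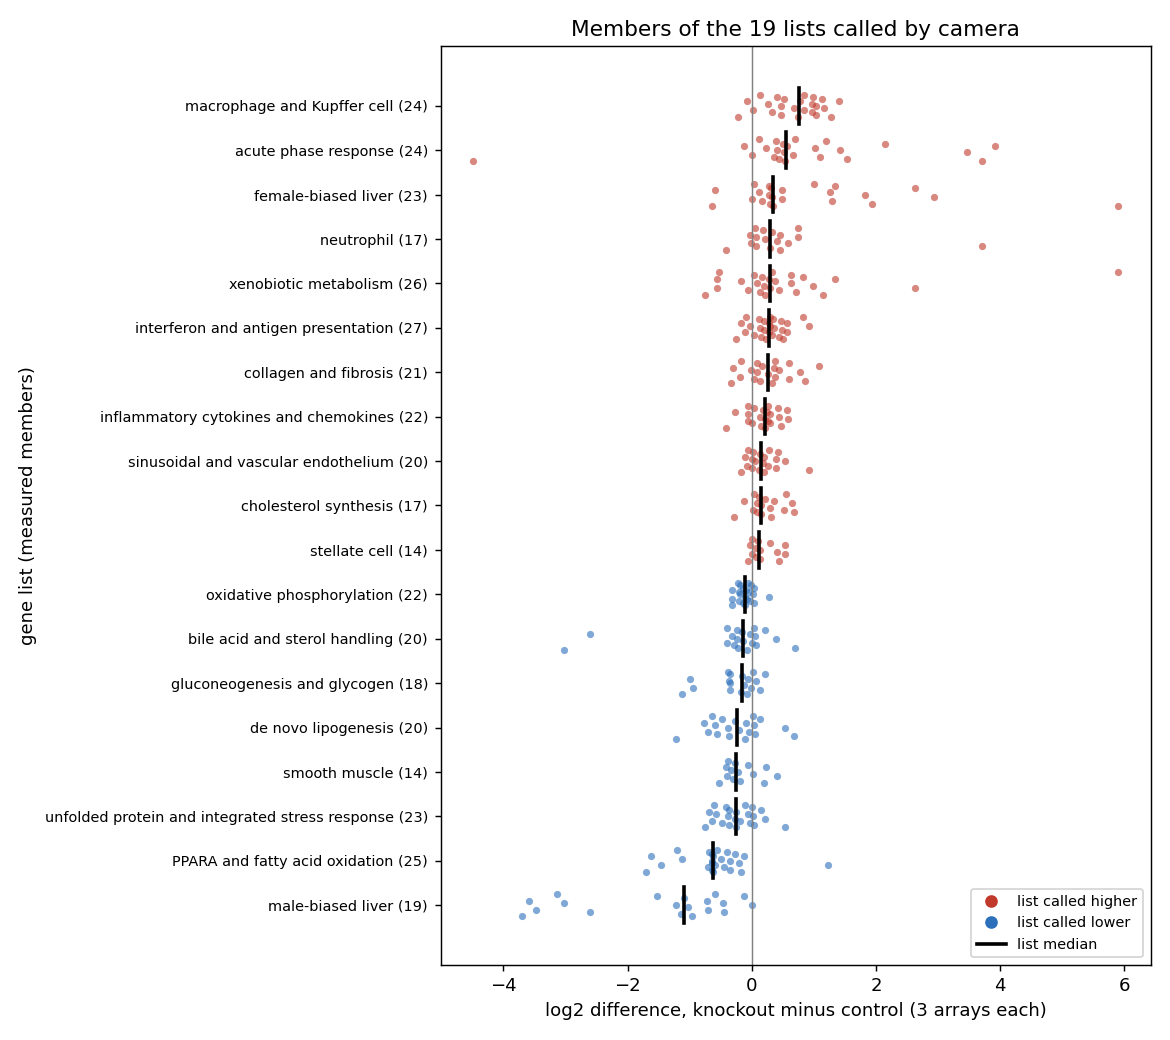
Log2 difference, knockout minus control, of every measured member of the 19 gene lists called by camera (horizontal axis, 3 arrays per group), 1 line per list with the number of measured members in brackets. Points are genes, red in lists called higher and blue in lists called lower, and the black bar is the list median, from 0.76 for macrophage and Kupffer cell genes to -1.09 for male-biased liver genes.

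Of 35 lists, camera called 19, 11 higher and 8 lower, and 0 of these calls held with an estimated correlation, where the smallest adjusted p was 0.280. For the neutrophil (-0.0442), cytokine (-0.00166), lipogenesis (-0.00809) and bile acid (0.00474) lists the estimated correlation lay under the preset 0.01. Correlation among their own members therefore does not account for the loss of these calls. Fry, which does not compare a list with other genes, called 2 lists, of which only neutrophil was among the 19. Across the 15 alternatives other than these 2 tests, 7 of the 19 lists were called every time, namely acute phase, macrophage, neutrophil, male-biased, female-biased, PPARA and collagen. By fry 6 of these 7 did not pass, with adjusted p-values of 0.0961 for acute phase, 0.169 for macrophage and 0.123 each for male-biased, female-biased, PPARA and collagen genes. Without control replicate 2 the number of called lists was 11.

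The cGMP signalling list, the pathway of the deleted kinase, was not called, with a median of 0.02 and a camera adjusted p of 0.752 over 22 members. Gucy2c was the only member that passed adjusted over the list alone, and Rgs2 (0.73, and 0.21 by a second, dimmer probe set), Nos1 (-0.35) and Pde5a (-0.30, dim in both groups) did not. Secreted and housekeeping hepatocyte genes had a median of 0.04 (adjusted p = 0.864), pericentral hepatocyte genes 0.06 (0.881) and periportal genes -0.01 (0.273). In the pericentral list Oat (-0.78) and in the periportal list Etnppl (-1.29) were lower adjusted over the list alone. Insulin signalling (median -0.11, adjusted p = 0.458) and cell cycle genes (0.07, 0.533) were not called, nor were markers of T and NK cells (0.16, 0.0798), B and plasma cells (0.07, 0.752), cholangiocytes (0.11, 0.184), erythroid cells (0.05, 0.475) and adipose tissue (0.09, 0.276). Of the 24 erythroid entries only 14 were measured. The T and NK list was the other list that fry called (adjusted p = 0.0294). Cd3e (0.61, from a dim control mean of 3.22) was its only member that passed adjusted over the list alone. Gzma (0.44), Eomes (0.43) and Cd3d (-0.37) did not pass. Pancreas and intestine markers had a median of 0.04 while their mean was -0.04 and camera's direction was lower (adjusted p = 0.672), and Fabp2 (-0.75), a fatty acid binding protein gene, was lower adjusted over the list alone.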

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

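Every alternative here was fixed before the data were examined, except the adjusted p under 0.10 and the lists without shared members, which were chosen after seeing the data. The count of 0 genes at an adjusted p under 0.05 moved to between 0 and 66 when single arrays were left out, the highest without knockout replicate 3 (66) and then control replicate 3 (3). It was 15 with the filter on dim probe sets, which leaves 13198 genes to adjust over, 25 with the intensity trend and 19 at an adjusted p under 0.10, and it stayed 0 with further quantile normalization, centring, the robust prior, array weights, averaged probe sets and every probe set tested. The count of 587 genes at an unadjusted p under 0.05 with at least 1.5-fold ranged from 551 to 870 without single arrays. It was 1654 over every probe set, a larger rise than that in features tested (41345 against 22180). With the same fold limit the count over genes was 376 at an unadjusted p under 0.01. At 1.2-fold it was 2334, the same as with no fold limit, so that limit removed no gene.

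The 19 called lists ranged from 11 to 20 without single arrays (11 without control replicate 2), were 0 with an estimated correlation and 2 with fry, and 16 without shared members. Fry ended the calls of 18 of the 19 lists. For the calls lost on leaving out an array the cause was not tested. The largest offset of an array median was 0.0321, and centring turned the 330 higher and 257 lower genes past the unadjusted threshold into 294 and 291. The Prkg1 difference stayed positive in every alternative, 0.04 to 0.23 without single arrays. The replicate numbers were not taken to pair the samples, since same-numbered arrays deviated from their group means with correlations of only 0.006 to 0.053 across genes, against -0.046 to 0.029 for other pairs, although knockout replicates 1 and 2 each correlated best in this way with the control of the same number, and knockout replicate 3 with control replicate 1. With the replicate block 1 gene passed (Elovl3), 20 lists were called, T and NK cell (adjusted p = 0.0472) and glucocorticoid (0.0449) among them and bile acid (0.0554) not, 616 genes lay past the unadjusted threshold and the Prkg1 difference was 0.11. Among the named genes without a call, signs turned on leaving out 1 array for Plin4 (-0.444 to 0.0855), Aqp7 (-0.000528 to 0.289), Vil1 (-0.165 to 0.0109), Reg1 (-0.0506 to 0.160) and, named after their values were seen, Hamp2 (-2.32 to 0.772) and Bmp6 (-0.545 to 0.0217), given as ranges over the 6 single arrays left out, and the cause was not tested. On arrays the signal over background limits dim genes, and the filter removed those with a mean at or below 3.11.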

Other observations

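Of the tests below, those on Xist, on Hamp2 and on other splits of the arrays were written before their results were seen, and the other tests of explanations, with the test of probe sets outside the gene test, were chosen after the result was seen. Circadian clock genes were not called as a list (19 members, median 0.06, camera adjusted p = 0.276), and 0 members passed over all genes or adjusted over the list alone. The clock repressor gene Nr1d1 had a difference of 0.74 (SE 0.20, limma adjusted p = 0.300), the output gene Dbp had 0.76 (SE 0.22, 0.321), and Tef (0.36), Hlf (0.30) and Nr1d2 (0.28), chosen after their values were seen, also had positive values, while those of Nfil3 (-0.62) and Noct (-1.22, and -1.80 with adjusted p = 0.0118 without knockout replicate 3) were negative. The hour of tissue collection is not given in the sources used here. Iron handling genes were not called (17 members, median -0.03, adjusted p = 0.912), and Hmox1 alone was higher adjusted over the list alone. Among the 19165 probe sets outside the gene test, limma gave 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 1982, more than the share of 0.05 expected with no difference.

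The male-biased list lay lower (median -1.09) and the female-biased list higher in the knockout. A female animal among the knockout samples is excluded by Xist, which was at 1.79 to 2.25 on all 6 arrays, the highest knockout array lying -0.14 from the highest control array, and the Y-linked gene Eif2s3y was at 5.55 to 6.24 on all of them. The Y-linked genes Uty (4.52 to 4.89 in the knockout arrays, 5.04 to 5.30 in the controls) and Kdm5d (3.40 to 4.09 and 4.24 to 4.43), both written into the same test, lay below every control array in all 3 knockout arrays. A general fall of hepatocyte transcripts would not set the male-biased list apart from other hepatocyte genes. The housekeeping hepatocyte list had a median of 0.0407, with a 95% bootstrap interval over members of -0.13 to 0.13. This argues against such a fall as the source of the male-biased difference. Whether most transcripts fell is not shown, because RMA would hide it, and the interval carries no spread between samples. An effect of the genotype is a hypothesis among others that stay open, and no test here bears on it.

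The macrophage and Kupffer cell list, with 1 of 24 measured members also in another list, lay higher (median 0.76). The macrophage median exceeded the endothelial median by 0.61 (95% bootstrap interval over members 0.27 to 0.86). A lower share of hepatocytes, raising all other cell types alike, would not give such a gap. The interval carries no spread between samples, and the members were correlated (estimated correlation 0.48 for macrophage and 0.59 for endothelial genes). This explanation is therefore not decided, and a blood leukocyte admixture also stays open. The macrophage median exceeded that of the pooled lymphocyte markers by 0.68 (0.29 to 0.90). Those markers, however, lay at a median control level of 2.997 against 3.14 for the whole table, too dim to show a small admixture. The brightest, Ighm, lay at 7.10 in the controls and 7.47 in the knockout, with every knockout array above every control array. Its other, dimmer probe sets also had positive differences (0.13 to 0.86), the direction that an admixture would give. Of the 12 B and plasma cell markers, 7 had positive and 5 negative differences. More macrophages, or more transcript per macrophage, could each give the higher macrophage values and were not tested.

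Hamp, encoding the iron hormone hepcidin, lay at 3.30 and 5.92 in knockout replicates 1 and 2, at 12.1 in knockout replicate 3 and at 11.1 to 11.8 in the controls (difference -4.49, SE 1.72, limma adjusted p = 0.413, with -2.59 without knockout replicate 1, and -6.97 with adjusted p = 0.00569 without knockout replicate 3). That replicate 3 was a mislabelled control is argued against by its median position between the control mean at 0 and the other knockout arrays at 1, which was 0.40 over the 66 genes that passed without it (95% bootstrap interval over genes 0.34 to 0.48) and 0.38 to 0.45 over 66 genes chosen without both it and 1 control array, where that left-out control array lay at 0.09, -0.02 or 0.09 (upper 95% prediction limit from these 3 arrays 0.37); the margin is narrow, replicate 3 correlated better with each control array (0.981 to 0.983) than with the other knockout arrays (0.978 and 0.979), though less than control arrays did with each other (0.989 to 0.990), and the genotype was not checked otherwise. A signal shared with the paralog Hamp2, named outside the rule after its value was seen although its test was written before, may contribute, since Hamp2 in knockout replicates 1 and 2 lay at least 1 log2 unit below the lowest control array, by -1.01 at the nearer of them, barely past the limit set; against it, Hamp2 was higher in knockout replicate 1 (4.28) than in 2 (2.62), the reverse of Hamp, and lay at 8.81 in knockout replicate 3, above the controls (5.29 to 6.60). Lower BMP and SMAD signalling stays open, because 2 of 4 target genes lay below all controls in both replicates, and of these Id1 did so by a very small margin (3.754 against 3.757) and was lowest, at 3.58, in knockout replicate 3, so that of the 4 only Atoh8 followed Hamp, as did the ligand gene Bmp6, chosen after its values were seen (3.43, 3.93 and 4.56 in knockout replicates 1 to 3, 4.10 to 4.29 in the controls). Tfrc, the transferrin receptor gene chosen after its values were seen, lay at 5.82, 6.24 and 4.44 in knockout replicates 1 to 3 and at 4.78 to 5.22 in the controls.

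The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 587 genes at an unadjusted p under 0.05 with at least 1.5-fold, against at most 251 in the other splits (1 of 10 as large), and 19 called lists against 4 to 13 (1 of 10 as large). At an adjusted p under 0.05 the real split gave 0 genes and the highest other split gave 1, and since any split reaches a count of 0 (10 of 10), this comparison says nothing.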
